A study of Mus musculus with 15 samples.

How the data were processed

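The deposited tables hold, per the file headers, counts and FPKM for 53465 genes in the 12 ICI and RI libraries, and FPKM alone in 34745 rows for the 3 RT libraries, where 59 gene names are listed more than once. Both units were checked against the values: the counts are whole numbers, and in 28458 of 28458 genes above 0 in at least 2 libraries the length implied by count, library total and FPKM was the same in all those libraries within 1%. The submitters' processing notes name HISAT2, GRCm38 and mm10 without versions; the counter, the annotation and the strand setting are not given in the sources used here. Of the 53465 gene identifiers 53274 were found in GENCODE M21, 51335 of them with the same chromosome, start and end (96.4%), and positions are given on GRCm38 from the deposited table. The FPKM of the 12 libraries served only for the levels set beside RT.

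Samples were matched to columns by their descriptions, and the 5 groups have 3 samples each. The number in a sample's title was not taken as a pairing: across pairs of libraries with the same number, deviations from the group means correlated at a mean r of 0.00638, from -0.344 to 0.301, and 3 of 12 libraries correlated best with their own number. In the descriptions the WT RI libraries are all of the naming JIAN, WT ICI 1 and 3 of TUI and 2 of JIAN, KD ICI 1 and 2 of JIAN and TUI with the same start H80, and KD ICI 3, KD RI 1 and KD RI 3 of SG793, with JIAN for KD RI 2. KD ICI 3 carries CON in its description, in the place where KD RI 1 and KD RI 3 carry ICI+RT. What these namings mean is not given in the sources used here.

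Counts were scaled by TMM, with factors from 0.852 to 1.00 in KD and 1.02 to 1.07 in WT, and genes were kept by filterByExpr (minimum count 10, minimum total count 15, by group), which left 16617. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries with robust shrinkage, and 6 contrasts were tested on both sides with Benjamini-Hochberg adjustment at 0.05 over all genes tested. The contrasts were KD against WT under ICI, under RI and on average, RI against ICI in WT and in KD, and the difference of those treatment effects. The common biological coefficient of variation was 0.209. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM on the TMM scale. By library totals before scaling 1 count is 0.0426 to 0.0578 CPM, and on the TMM scale it is 0.0680 CPM in KD ICI 1. A gene with no count in a group has its fold bounded by 3 counts over the group. Planned tests of RI against RT and RT against ICI in KD were left out, as laid down for the case of a separate table.

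Gene lists, contrasts, the test, the threshold and the rule for named genes were set before the data were examined. The lists cover fibroblast matrix, myofibroblast, inflammatory fibroblast, pericyte, endothelial, Wnt, T cell, cytotoxic, checkpoint, regulatory T cell, B and plasma cell, macrophage, neutrophil, dendritic, interferon, class I, class II, cytokine, p53, proliferation, hypoxia, epithelial-mesenchymal, CREB, AMPK, oxidative phosphorylation, lipid, venule adhesion, mast cell, stress and mitochondrially encoded genes. Further lists hold markers of muscle, keratinocytes, adipocytes, erythroid and Schwann cells. Lists with at least 5 members measured, 33 of them, were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over all lists and contrasts together. In each contrast camera with an estimated correlation called 0 of the lists that the preset called (14, 11, 15, 15, 15 and 18), and fry, a self-contained set test, called 12, 15, 17, 4, 4 and 9.

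By rule, the named genes were Stk11 and Sfrp2, the 8 genes of largest change in each direction past the threshold with no overlap between groups, at least 2 CPM in the higher group and no predicted-gene name, and up to 2 members rising and 2 falling in each list. In a list that passed with no member past the threshold, the 2 members of smallest p were named. From the genes so named a smaller set was picked for the text after their values were seen, with weight on genes of known function. In some lists where 5 or fewer members passed, these are named outside the rule. So are genes among the 14 of RI against ICI in KD and Acta1, Hbb-bs, Ddx3y and Xist, chosen after their values were seen.

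A self-test on simulated counts with the fitted dispersions planted changes in 67, 67 and 66 genes, and in a list of 20 further genes. Of 1.5-fold, 2-fold and 4-fold changes the test recovered 16.4%, 64.2% and 90.9% for KD against WT under ICI. For the difference of treatment effects it recovered 2.99%, 31.3% and 72.7%. False calls were 5 in the former and 6 in the latter, 3.88% and 7.32% of calls. The simulation drew genes independently, with no structure among the libraries of a group. It changed few of 16273 genes, while 31.0% passed in the data for KD against WT under ICI. Recovery and false calls in the data may therefore differ. No pair of libraries within a group was closer than counting noise allows.

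Alternatives changed 1 choice at a time: DESeq2, scaling by library size alone or RLE, no filter or a minimum of 1 CPM in 3 samples, the groups compared alone, the title number as block, the naming series as covariate, the H80 libraries summed into 1, and leaving out each library. After seeing the data, 4 more were added: KD against WT within the JIAN libraries with treatment as a term, leaving out WT ICI 2 and WT RI 3 with high muscle transcripts, leaving out the SG793 libraries, and muscle transcripts as covariate. Software was Python 3.11.15, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.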

Results

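The libraries come from tumours of the mouse Lewis lung carcinoma line LLC1, either wild type (WT) or sgLkb1, whose genotype label is LKB1 knockdown (KD). Tumours had an immune checkpoint inhibitor (ICI) or radiation with ICI (RI), 3 libraries per group, and a further 3 KD libraries had radiation alone (RT). No sample is labelled untreated and none is WT with RT. KD ICI 3 is labelled ICI but carries CON in its description, in the place where KD RI 1 and KD RI 3 carry ICI+RT. CON is therefore at odds with the ICI label and may stand for an untreated control. Its meaning is not given in the sources used here, and the library was kept as ICI in every test. Counts were deposited for the 12 ICI and RI libraries, which hold 17289313 to 23471917 counts each, and 16617 genes passed the filter on low counts. The first principal component of log2 CPM carried 52.7% of the variance and the second 12.3%. Tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and p-values measure only the spread between samples, since the labels do not say that the samples are separate animals. Changes are given below as log2 fold change with its standard error and then adjusted p, and levels as mean CPM with the standard deviation of 3 libraries.

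**Figure D1:**
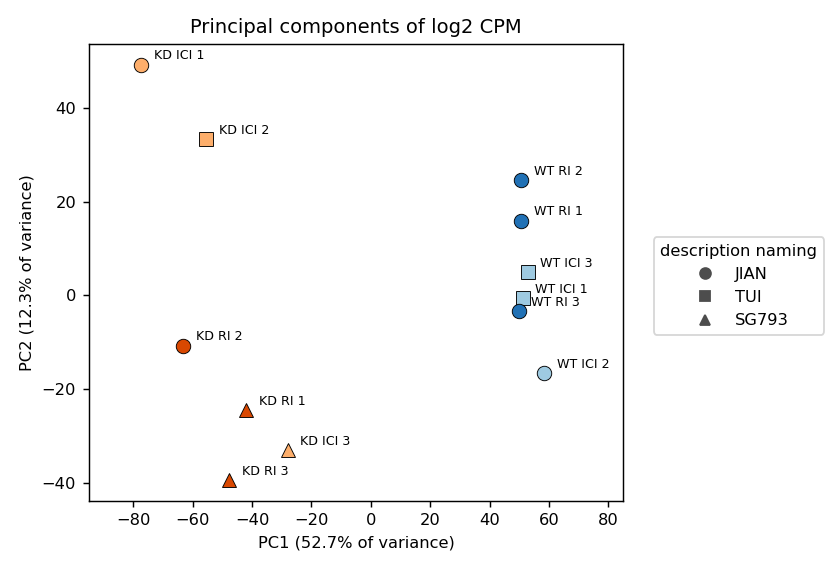
Principal components 1 (52.7% of variance) and 2 (12.3%) of log2 CPM for the 12 libraries with counts. Each point is 1 library, coloured by group, with marker shapes for the naming in the description (circle JIAN, square TUI, triangle SG793).

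Stk11, which encodes the kinase LKB1 (chromosome 10, 80115803 to 80130682), was measured first as the target of the guide. It stood at 168, 152 and 171 CPM in WT ICI libraries 1 to 3 and 140, 140 and 147 in WT RI. The KD values were 115, 128 and 152 CPM under ICI and 139, 111 and 127 under RI. Within each treatment every KD library lay below every WT library, and chance separates 3 from 3 libraries, in 1 direction or the other, for 10% of genes. Of the 16617 genes tested, 6924 were so separated under ICI and 7502 under RI, so this separation is common here and does not single out Stk11. The change was -0.31±0.11 under ICI (adjusted p = 0.0556) and -0.18±0.12 under RI (adjusted p = 0.304), neither past the threshold. Averaged over both treatments Stk11 fell by 0.25±0.08 (adjusted p = 0.0283). That average lost its call without KD ICI 1 (0.0614), KD ICI 2 (0.0557), KD RI 2 (0.0737), KD RI 3 (0.0532), WT ICI 1 (0.0535) or WT ICI 3 (0.0579). KD ICI 1 and 2 share H80 in their descriptions, and with those libraries summed into 1 the average also missed the threshold (0.0559). The ICI change passed without KD ICI 3 (0.00455) or KD RI 2 (0.0483). RNA levels do not show whether the guide removed the protein, and libraries from tumours also hold host cells. These values therefore do not measure how far LKB1 was lost in the tumour cells. 

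Sfrp2, a secreted Wnt modulator of fibroblasts named in the series title (chromosome 3, 83766321 to 83774316), was low in every group. Its means were 1.62±1.16 CPM in WT ICI, 2.43±1.62 in WT RI, 2.71±0.203 in KD ICI and 8.10±4.38 in KD RI. No test of Sfrp2 passed: KD against WT gave 0.75±0.68 under ICI (adjusted p = 0.423), 1.74±0.66 under RI (0.0851) and 1.25±0.47 on average (0.0534). The RI change passed without WT ICI 2 (0.0291) or WT RI 3 (0.0446), and the average without KD RI 3 (0.0285) or WT RI 3 (0.0240) and within the JIAN libraries alone (2.55, 0.0139). RI against ICI gave 0.59±0.68 in WT (0.829), 1.57±0.66 in KD (0.304) and a difference of 0.98±0.94 (0.688).

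**Figure D2:**
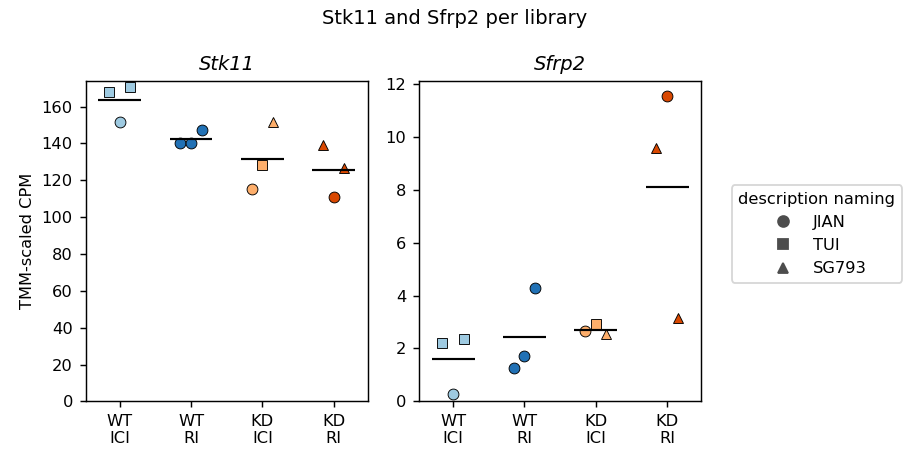
Stk11 and Sfrp2 in TMM-scaled CPM, 1 point per library and a line at each group's mean. Marker shape gives the naming used in the sample description: circle JIAN, square TUI, triangle SG793.

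Under ICI most T cell, interferon, class I and class II list genes were lower in KD than in WT tumours, and most neutrophil, hypoxia and CREB target list genes higher. As lists they passed with camera's preset correlation, but not with an estimated one (0.130, 0.299, 0.190, 0.281, 0.351, 0.228 and 0.145). Cd8a, the CD8 co-receptor of cytotoxic T cells, fell by 4.24±0.42 (adjusted p = 5.70e-05), from 4.79±1.51 to 0.245±0.0361 CPM (n = 3 and 3). Cd274, which encodes PD-L1, fell by 1.40±0.15 (7.54e-05), from 27.0±3.13 to 10.2±1.46 CPM. Pde4b, a cAMP phosphodiesterase, rose by 3.47±0.21 (5.31e-06), from 13.8±3.00 to 154±7.57 CPM. Vegfa, the hypoxia-induced angiogenic factor, rose by 1.83±0.24 (0.000285), from 110±36.7 to 389±32.1 CPM. In all, 2672 genes were higher and 2474 lower in KD, 5146 past the threshold, and 2250 of them changed more than 2-fold.

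All 16 T cell list genes fell under ICI, and 16 did when adjusted over the list alone, with a median log2 fold change of -3.14 (camera adjusted p = 1.70e-11, but adjusted p = 0.130 with an estimated correlation). Among 14 cytotoxic list genes 11 fell, 12 over the list alone, and Eomes rose (list 6.42e-06, and 0.228 with an estimated correlation). Eomes kept that call in 2 of the 12 fits that leave out 1 library, those without KD ICI 1 or KD ICI 2. Ccl5, which draws T cells, fell by 2.45±0.32 (0.000268), from 11.5 to 2.09 CPM, and Nkg7, of cytotoxic granules, by 2.89±0.38 (0.000272). Of 12 checkpoint list genes 7 fell, also 7 over the list alone (0.00140, and 0.130 with an estimated correlation), though 4 without WT ICI 1. Pdcd1, which encodes PD-1, fell by 3.56±0.68 (0.00253), from 2.75 to 0.216 CPM.

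Macrophage list genes fell in 12 of 17 cases and rose in 1, with 13 falling and 1 rising over the list alone and a median of -1.40 (adjusted p = 9.14e-06, and 0.228 with an estimated correlation). C1qb and C1qc, complement subunits made by macrophages, fell by 1.81±0.19 (7.54e-05, 201±11.7 to 57.3±18.2 CPM) and 1.94±0.21 (0.000108, 166 to 43.3 CPM). Spp1, a secreted protein of tumour cells and macrophages, rose by 0.91±0.26 (0.0193), from 1255 to 2356 CPM, a call lost without KD ICI 1 (0.0632) or WT ICI 2 (0.0618), and also with library size alone, with no filter on low counts, with only the groups compared and without the SG793 libraries. Dendritic list genes fell in 6 of 10 cases, 7 over the list alone (0.00971, and 0.219 with an estimated correlation), with 3 falling without KD ICI 1 and 3 without WT ICI 1. Flt3, the growth factor receptor of dendritic progenitors, instead rose by 2.97±0.49 (0.00133), from 2.75 to 21.6 CPM. Neutrophil list genes rose in 10 of 13 cases, 11 over the list alone, with a median of 2.79 (9.21e-05, and 0.351 with an estimated correlation). Their mean log2 CPM went down across KD ICI 1, 2 and 3 (5.12, 4.26 and 3.12) along with erythroid genes (7.31, 5.94 and 4.02), while proliferation genes went up (6.05, 6.44 and 7.29). Clec4d, a myeloid lectin on that list, rose by 1.25±0.24 (0.00231), from 23.5 to 55.9 CPM.

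Of 25 interferon list genes 22 fell under ICI and Oasl1 rose, the same counts over the list alone, with a median of -1.27 (adjusted p = 9.88e-10, and 0.299 with an estimated correlation). The guanylate-binding gene Gbp3 fell by 2.28±0.22 (adjusted p = 5.12e-05). MHC class I list genes fell in 13 of 15 cases, 14 over the list alone (8.25e-09, and 0.190 with an estimated correlation). Psmb9, an immunoproteasome subunit, fell by 1.70±0.12 (2.22e-05), from 39.8 to 12.3 CPM. MHC class II list genes fell in 6 of 8 cases, 6 over the list alone, with a median of -2.83 (0.000173, and 0.281 with an estimated correlation). H2-DMa, which loads class II peptides, fell by 2.01±0.22 (9.79e-05), and Ciita, the class II master regulator, by 2.83±0.64 (0.00616), from 6.38 to 0.874 CPM.

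Hypoxia and glycolysis list genes rose under ICI in 16 of 18 cases, 16 over the list alone, with a median of 0.92 (adjusted p = 2.64e-07, and 0.228 with an estimated correlation). Fewer rose without KD ICI 1 (10), WT ICI 1 (9), WT ICI 2 (8) or WT ICI 3 (7). The 18 members, here and below, count 1 gene symbol under 2 gene identifiers. Adm, a hypoxia-induced vasodilator peptide, rose by 2.45±0.33 (0.000425), from 28.2 to 154 CPM. CREB target list genes rose in 8 of 13 cases, 10 over the list alone (2.30e-05, and 0.145 with an estimated correlation). Sik1, a kinase that LKB1 activates and CREB induces, rose by 2.05±0.18 (3.39e-05), from 40.1 to 166 CPM. Stress list genes Atf3 and Jun rose out of 10, and 5 rose over the list alone (0.00930, and 0.5 with an estimated correlation); 7 rose without KD ICI 2 and 4 without KD RI 3, and the list did not pass without KD ICI 3 (0.162). The interleukin 6 family cytokines Il11 and Lif rose by 5.23±0.73 (0.000846, 3.41 to 127 CPM) and 4.02±0.50 (0.000372, 7.07 to 114 CPM). Cytokine list genes as a group did not shift: 5 of 16 rose (Ptgs2, Cxcl1, Cxcl2, Il11, Csf3) and 5 fell (Csf1, Ccl7, Ccl3, Ccl4, Tnf), 5 and 6 over the list alone, with a median of -0.20 against a mean of 0.42 (adjusted p = 0.864).

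Stromal genes moved in both directions under ICI. Fibroblast list genes rose in 3 of 22 cases (Ctsk, Dcn, Sfrp1) and fell in 1 (Col5a2), with a median of -0.13 against a mean of 0.17 (adjusted p = 0.955). Dcn, a matrix proteoglycan, rose by 1.59±0.40 (0.0127), from 55.5 to 167 CPM, and the collagenase Ctsk by 3.31±0.78 (0.0112), from 9.27 to 91.4 CPM. The Dcn call was lost without the SG793 libraries and with no filter on low counts, and the Sele call below with no filter. Pericyte list genes rose in 3 of 12 cases (Kcnj8, Abcc9, Notch3) and fell in 2 (list 0.826): Notch3 rose by 2.08±0.27 (0.000257), while Rgs5 fell by 1.65±0.36 (0.00532) and Pdgfrb, the mural growth factor receptor, by 1.26±0.24 (0.00217), from 39.7 to 16.6 CPM. Endothelial list genes rose in 3 of 15 cases, 2 over the list alone, and fell in 1 (list 0.531): Cdh5, the endothelial cadherin, rose by 1.17±0.25 (0.00506), from 30.6 to 69.2 CPM. The adhesion genes of lymphocyte entry split, with Icam1 lower by 1.97±0.23 (0.000121), Vcam1 lower by 1.49±0.18 (0.000172) and Sele higher by 3.72±0.94 (0.0117); the high endothelial venule list had a median of -0.82 against a mean of 0.21 (0.306). Wnt list genes rose in 4 of 14 cases (Dkk2, Wnt2, Sfrp1, Wnt5a) and fell in 1 (Tcf7; list 0.464). Dkk2, a Wnt antagonist, rose by 2.74±0.56 (0.00537), from 43.4 to 289 CPM, and the ligand Wnt2 by 2.60±0.48 (0.00212). The 3 pericyte genes that rose were 1 without KD ICI 1, WT ICI 1, WT ICI 2, WT ICI 3 or WT RI 2, the 4 Wnt genes were 2 without KD ICI 1, WT ICI 1, WT ICI 2 or WT ICI 3, and the 3 endothelial genes were 1 without KD ICI 1, WT ICI 1 or WT ICI 2 and 5 without KD ICI 3. The 1 fibroblast gene that fell became 4 without KD ICI 2, 3 without KD RI 3, 2 without KD RI 1, WT ICI 1, WT RI 1 or WT RI 3, and 0 without KD ICI 3. The 1 Wnt gene that fell became 2 without KD ICI 2 or KD RI 1 and 3 without KD ICI 3, and the 1 endothelial gene became 0 without KD ICI 2.

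Further genes changed strongly under ICI. Sall1, a developmental zinc finger factor, had no count in the 3 KD libraries against 5.21 CPM in WT, at least 96.8-fold lower at a bound of 3 counts over the group (adjusted p = 2.24e-05). Smoc1, a matricellular calcium-binding protein, fell by 6.18±0.28 (4.09e-07), from 14.4 to 0.182 CPM, and the ligand Wnt6 by 4.93±0.32 (7.45e-06), from 6.70 to 0.210 CPM. In the other direction Gad1, the GABA-making enzyme, rose by 6.96±1.21 (0.00205), from 0.137 to 16.9 CPM. Osbp2, an oxysterol-binding protein, rose by 6.48±1.31 (0.00642), from 4.14±5.81 to 362±100 CPM. The squamous protease gene Tmprss11f rose by 6.79±1.03 (0.00106), from 0.212 to 23 CPM; related genes share sequence, so its reads are uncertain.

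Proliferation list genes were mostly short of the threshold under ICI: 4 of 23 fell (Cenpf, E2f1, Ccna2, Mcm4), 0 over the list alone, with a median of -0.34 (adjusted p = 0.00227, and 0.712 with an estimated correlation). The count was 22 without KD ICI 3. It was 0 without KD ICI 1, KD ICI 2, WT ICI 1 or WT ICI 2, 1 without WT ICI 3, and 2 without KD RI 1, KD RI 3, WT RI 1 or WT RI 2, and the list did not pass without KD ICI 1 (0.0969). The erythroid list also passed (0.0253, and 0.552 with an estimated correlation) with Slc4a1 the 1 gene of 6 to rise, and 6 without WT ICI 2. It did not pass without KD ICI 1 (0.0719), WT ICI 1 (0.0573) or WT ICI 3 (0.0560). Hbb-bs, a haemoglobin gene whose family shares sequence, stood at 1284 CPM in KD ICI 1, 452 in KD ICI 2, 105 in KD ICI 3 and 379 in WT ICI 2. Acta1, of skeletal muscle, stood at 340 CPM in WT ICI 2 and 310 in WT RI 3 against 39.2 or less elsewhere; no muscle list gene of 11 changed in either genotype comparison (0.0972 under ICI, 0.622 under RI). The muscle median was -4.62 under ICI, a list that passed without WT ICI 1 (0.0307), WT ICI 3 (0.0225) or WT RI 3 (0.0255). Under RI the median was -2.22 while the test leaned upward, and it passed without WT RI 3 (0.00204).

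The remaining lists did not pass for KD against WT under ICI. Genes of the LKB1 and AMPK pathway rose in 3 of 14 cases (Cab39, Sik3, Prkaa1) and fell in 2 (Nuak2, Prkag2; list adjusted p = 0.311, median 0.18 against a mean of -0.15). B and plasma cell genes fell in 1 of 7 cases (Cd22; 0.273), regulatory T cell genes in 1 of 6 (Il2ra; 0.0896) and mast cell genes in 3 of 5, 4 over the list alone (0.103). The 3 mast cell genes became 0 without KD ICI 1 or WT ICI 3 and 1 without KD ICI 2 or WT ICI 1, and that list passed without WT RI 2 (0.0426). Myofibroblast genes rose in 4 of 10 cases and fell in 1 (0.177), inflammatory fibroblast genes rose in 3 of 12 and fell in 3 (0.968, median -0.04 against a mean of 0.11), and epithelial-mesenchymal genes rose in 4 of 14 and fell in 2 (0.599). Mitochondrially encoded genes fell in 2 of 9 cases (0.0714), oxidative phosphorylation genes rose in 1 of 16 and fell in 3 (0.945), and lipid genes rose in 1 of 15 (Srebf2; 0.622), a call lost without KD ICI 2, KD ICI 3 or any 1 WT library. The mitochondrial list passed without KD ICI 2 (0.00902) or KD RI 3 (0.0383), the 4 myofibroblast genes became 2 without KD ICI 1 or WT ICI 3, and the 3 inflammatory fibroblast genes that fell became 5 without WT RI 3. Targets of p53 rose in 2 of 18 cases and fell in 1 (0.299), and Fabp4 was the 1 of 6 adipocyte genes to rise (0.411), which it did not without KD ICI 1, KD ICI 2, KD RI 1, KD RI 3, WT RI 1 or any 1 WT ICI library. Only 1 keratinocyte gene was measured (Sfn, lower by 0.95), and 0 of 3 Schwann genes changed; neither list was tested as a group. Leaving out KD ICI 2, there were 3 B cell, 4 mitochondrial and 0 p53, myofibroblast and keratinocyte genes that fell, and 2 oxidative phosphorylation genes that rose. The 2 epithelial-mesenchymal genes that fell became 1 without KD ICI 1, KD ICI 2, KD RI 3, WT ICI 2, WT ICI 3 or WT RI 2. Leaving out KD ICI 3, there were 5 p53 and 2 oxidative phosphorylation genes that rose, and 2 p53, 1 mitochondrial and 0 myofibroblast genes that fell. The 2 mitochondrial genes became 0 without KD ICI 1, WT ICI 1 or WT ICI 2, the 1 myofibroblast gene that fell 0 without any 1 WT ICI library, and the 1 p53 gene that fell and the 1 oxidative phosphorylation gene that rose 0 without WT ICI 1 or WT ICI 3.

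Under RI most T cell, interferon, class I and class II list genes were again lower in KD, as lists past the threshold with the preset correlation but not with an estimated one (0.125, 0.171, 0.125 and 0.174), while the hypoxia list did not pass. Cd8a fell by 5.42±0.44 (adjusted p = 6.77e-06), from 9.29 to 0.210 CPM (n = 3 and 3), and Gzmb, the cytotoxic granule protease, by 4.55±0.39 (1.43e-05), from 55.6 to 2.37 CPM. Cd274 fell by 3.00±0.15 (2.31e-07), from 54.3±5.83 to 6.79±0.752 CPM. Cxcl9, the interferon-induced T cell chemokine, fell by 6.80±0.83 (0.000367), from 97.5±35.6 to 0.863±0.134 CPM. Dcn rose by 2.39±0.41 (0.00213), from 35.4 to 185 CPM. In all, 1525 genes were higher and 2003 lower in KD, 3528 past the threshold, and 1737 of them changed more than 2-fold.

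All 16 T cell list genes fell again under RI, with a median of -4.50 (adjusted p = 4.53e-16, and 0.125 with an estimated correlation). Cytotoxic list genes fell in 12 of 14 cases, 13 over the list alone where 1 rose (4.54e-11, and 0.130 with an estimated correlation), and Ccl5 fell by 3.57±0.34 (2.31e-05). Checkpoint list genes fell in 10 of 12 cases, 12 over the list alone (1.56e-09, and 0.0568 with an estimated correlation); Ctla4 fell by 4.51±0.53 (9.85e-05), from 3.35 to 0.141 CPM. Regulatory T cell genes fell in 1 of 6 cases (0.0418, and 0.379 with an estimated correlation), a call lost without KD ICI 3 (0.0625), KD RI 3 (0.0630), WT RI 1 (0.0661) or WT RI 2 (0.0903); 2 fell without KD RI 1 or KD RI 2. Macrophage list genes fell in 14 of 17 cases, 14 over the list alone (1.11e-08, and 0.145 with an estimated correlation), with C1qb down by 1.90±0.19 (3.24e-05) and C1qc by 1.90±0.21 (7.82e-05). Cytokine list genes fell in 7 of 16 cases, 8 over the list alone (0.00962, and 0.5 with an estimated correlation), while Il11 rose by 3.70±0.67 (0.00352), from 7.11 to 92.8 CPM. Flt3 rose by 4.20±0.54 (0.000252), with dendritic genes falling in 3 of 10 cases (list 0.376).

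Of 25 interferon list genes 23 fell under RI, 24 over the list alone, with a median of -2.14 (adjusted p = 3.71e-20, and 0.171 with an estimated correlation). Gbp3 fell by 4.27±0.24 (5.42e-07), from 59.3 to 3.06 CPM, Irf1, an interferon transcription factor, by 2.40±0.16 (1.76e-06), from 161 to 30.4 CPM, and the interferon GTPase Tgtp1 by 7.28±0.56 (4.73e-06), from 14.7 to 0.0889 CPM. All 15 class I list genes fell (7.76e-20, and 0.125 with an estimated correlation), with Psmb9 down by 2.69±0.13 (1.26e-07). H2-Q7, a class Ib gene, fell by 4.67±0.24 (2.31e-07), from 114 to 4.46 CPM, though it shares sequence with its neighbours, which leaves its reads uncertain. All 8 class II list genes fell (1.84e-07, and 0.174 with an estimated correlation), with H2-DMa down by 3.06±0.23 (4.73e-06) and Ciita by 4.14±0.73 (0.00174).

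Fibroblast list genes rose under RI in 8 of 22 cases (Col5a1, Postn, Ctsk, Col1a2, Dcn, Sfrp1, Sparc, Col1a1), 10 over the list alone, with a median of 0.83 (adjusted p = 0.000214, and 0.390 with an estimated correlation). The count was 5 without KD RI 1, KD RI 2, WT RI 1 or WT RI 2. Col5a1, a fibrillar collagen chain, rose by 0.90±0.17 (0.00238), from 82.1 to 153 CPM. Wnt list genes rose in 4 of 14 cases (Dkk2, Wnt2, Dkk3, Sfrp1), 7 rising and 1 falling over the list alone (0.0413, and 0.341 with an estimated correlation), and the list did not pass without KD ICI 3 (0.0529) or KD RI 1 (0.134). Dkk2 rose by 3.46±0.58 (0.00224), from 20.8 to 229 CPM, Wnt2 by 3.43±0.50 (0.000506) and Notch3 by 2.18±0.27 (0.000153). Pericyte list genes rose in 4 of 12 cases (0.0872) and Cdh5 rose by 1.08±0.25 (0.00943), the 1 endothelial gene of 15 to do so (0.994, median -0.07 against a mean of 0.02). Icam1 fell by 2.87±0.24 (8.06e-06) and Vcam1 by 1.59±0.18 (7.12e-05), while the venule list did not pass (0.0926). Sele rose by 2.99±0.92 (0.0380), a call lost without KD ICI 2 (0.0526), KD ICI 3 (0.0584), KD RI 2 (0.255), WT ICI 3 (0.0537), WT RI 1 (0.122) or WT RI 2 (0.121). It was also lost with the H80 libraries summed into 1, the title number as block, no filter or only the groups compared, and the Cdh5 call without the muscle-rich libraries WT ICI 2 and WT RI 3. The 1 endothelial gene became 2 without KD ICI 1.

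Hypoxia list genes split, with Vegfa higher by 0.79±0.23 (adjusted p = 0.0285) and the glycolytic kinase Hk2 lower by 1.07±0.17 (0.000691), from 247 to 117 CPM (list 0.852). The Vegfa call was lost without KD RI 1 (0.0761), KD RI 2 (0.108), WT RI 1 (0.101) or WT RI 3 (0.119), and also with no filter or without the SG793 libraries, which leaves 1 library in KD RI. The hypoxia genes that rose were 2 without KD RI 3, and those that fell 2 without KD RI 2. Pde4b rose by 2.72±0.21 (4.76e-06) and its relative Pde4d by 3.06±0.30 (2.66e-05), from 2.22 to 18.6 CPM; CREB list genes rose in 4 of 13 cases and fell in 1 (0.0714). Nuak2, an AMPK-related kinase that LKB1 activates, fell by 2.38±0.33 (0.000282), from 9.61 to 1.84 CPM; its pathway list did not pass (0.734). Smoc1 fell by 7.09±0.29 (6.26e-08), from 22.5 to 0.160 CPM, and Gap43, a growth cone protein, rose by 6.36±0.84 (0.000644), from 1.84 to 151 CPM. Neutrophil genes rose and fell in 1 case each of 13 (Mmp9, Il1b; 0.866, median 0.20 while the test leaned downward). The count that rose was 0 without KD ICI 1, WT ICI 3 or any 1 RI library, and the count that fell was 0 without KD RI 1, KD RI 3, WT RI 1 or WT RI 2 and 2 without KD ICI 3 or KD RI 2. Proliferation genes fell in 1 of 23 cases (0.277).

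The other lists did not pass under RI. Mast cell genes fell in 2 of 5 cases (adjusted p = 0.0509), mitochondrially encoded genes in 2 of 9 (0.0569) and B cell genes in 2 of 7 (0.149). Myofibroblast genes rose in 1 of 10 cases and fell in 1 (0.106), inflammatory fibroblast genes rose in 2 of 12 and fell in 3 (0.734), and epithelial-mesenchymal genes rose in 2 of 14 and fell in 3 (0.941). Oxidative phosphorylation genes rose in 2 of 16 cases and fell in 2 (0.378), p53 targets rose in 1 of 18 and fell in 2 (0.535), and stress genes fell in 1 of 10 (0.535). Lipid, adipocyte and erythroid genes changed in 0 cases (0.602, 0.935 and 0.736), the adipocyte median being -2.10 while its test leaned upward. Without 1 library some lists passed: mast cell genes in 8 such fits (lowest 0.00712, without WT RI 1), mitochondrial genes in 5 (lowest 0.00483, without KD RI 3), B cell genes without KD ICI 2 (0.0368) or WT RI 1 (0.0409), and adipocyte genes without WT RI 3 (0.0300). Myofibroblast genes did so without KD RI 3 (0.0332) or WT RI 3 (0.0400), pericyte genes without the same (0.0236 and 0.0408), CREB genes likewise (0.0318 and 0.0367), and venule genes without WT RI 1 (0.0449). Counts moved too: the 2 oxidative phosphorylation genes that rose became 4 without KD ICI 1, 7 without KD ICI 3 and 1 without KD RI 2, KD RI 3, WT ICI 3 or any 1 WT RI library. The 2 p53 genes that fell became 5 without KD ICI 3 and 1 without KD RI 1, KD RI 3 or WT RI 3, and the 1 that rose became 2 without KD ICI 2 or KD ICI 3 and 0 without KD RI 1, KD RI 3, WT RI 1 or WT RI 2. The 2 mast cell genes became 0 without KD RI 2 or WT RI 2 and 1 without KD RI 1, KD RI 3 or WT ICI 1, and the 2 mitochondrial genes became 4 without KD ICI 3 and 1 without KD RI 1, KD RI 2 or any 1 WT RI library. The 2 B cell genes became 4 without KD ICI 2 and 1 without KD RI 3, and the 1 myofibroblast gene that rose became 0 without KD RI 1, KD RI 2, WT RI 1, WT RI 2 or any 1 WT ICI library. Leaving out KD ICI 3 gave 4 proliferation and 2 stress genes that fell, and the 2 inflammatory fibroblast genes that rose became 1 without KD RI 2, KD RI 3 or WT RI 2. The count of proliferation genes that fell was 2 without KD ICI 1, and that of epithelial-mesenchymal genes that rose was 1 without WT RI 1.

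KD and WT differed alike under both treatments for 1077 genes higher and 1331 lower, against 245 and 298 by chance, with 16 genes in opposite directions, and log2 fold changes correlated at r = 0.752. Averaged over both treatments 3351 genes were higher and 3410 lower, 6761 in all. Smoc1 (-6.63±0.20, adjusted p = 2.88e-09), Cd274 (-2.20±0.11, 7.45e-08), Nuak2 (-1.76±0.22, 7.06e-05) and Pde4b (3.10±0.15, 7.45e-08) were among them. On average 16 of 16 T cell genes, 15 of 15 class I, 8 of 8 class II, 23 of 25 interferon and 11 of 12 checkpoint genes fell. Scaling by library size alone moved the count of genes under ICI to 1564 higher and 4141 lower (median shift -0.21), under RI to 1149 and 2278 (-0.07) and on average to 2062 and 4599 (-0.14), so the balance of higher and lower rests on TMM. Without KD ICI 3, which leaves KD ICI with only the libraries that share H80, the count of genes under ICI was 7827. The naming series of the descriptions (JIAN, TUI, SG793) allow KD against WT within JIAN alone, 2 KD against 4 WT libraries with treatment in the model, a fit chosen after seeing the data: 4514 genes passed, 4013 of them shared with the 6761, and all 16 T cell genes fell. TUI holds 1 KD and 2 WT libraries, SG793 holds no WT library, and neither genotype within these nor treatment within a series was fitted. With the series as a covariate 6939 genes passed under ICI, 4918 of them shared with the 5146, and 4867 under RI, 2949 shared with the 3528. Ddx3y, a Y gene, stood at 5.15 CPM in KD ICI 3, 3.55 in KD RI 1 and 2.34 in KD RI 3, all of the SG793 naming, and at 0.636 or less elsewhere. Xist, the transcript of the inactive X, stood at 1.61, 0.388 and 0.208 CPM in these libraries and from 33.8 to 107 CPM elsewhere. Hosts thus seem male in SG793 and female elsewhere, all WT libraries included. Low Y transcripts were still found in WT: Eif2s3y, another Y gene, was at 0.0476 to 0.916 CPM there. It had 0 counts in KD ICI 1, KD ICI 2 and KD RI 2, as did Ddx3y. What the low levels in WT come from was not tested. Host sex is mixed into KD against WT and was in no model, but the JIAN libraries hold none of the male pattern.

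**Figure D3:**
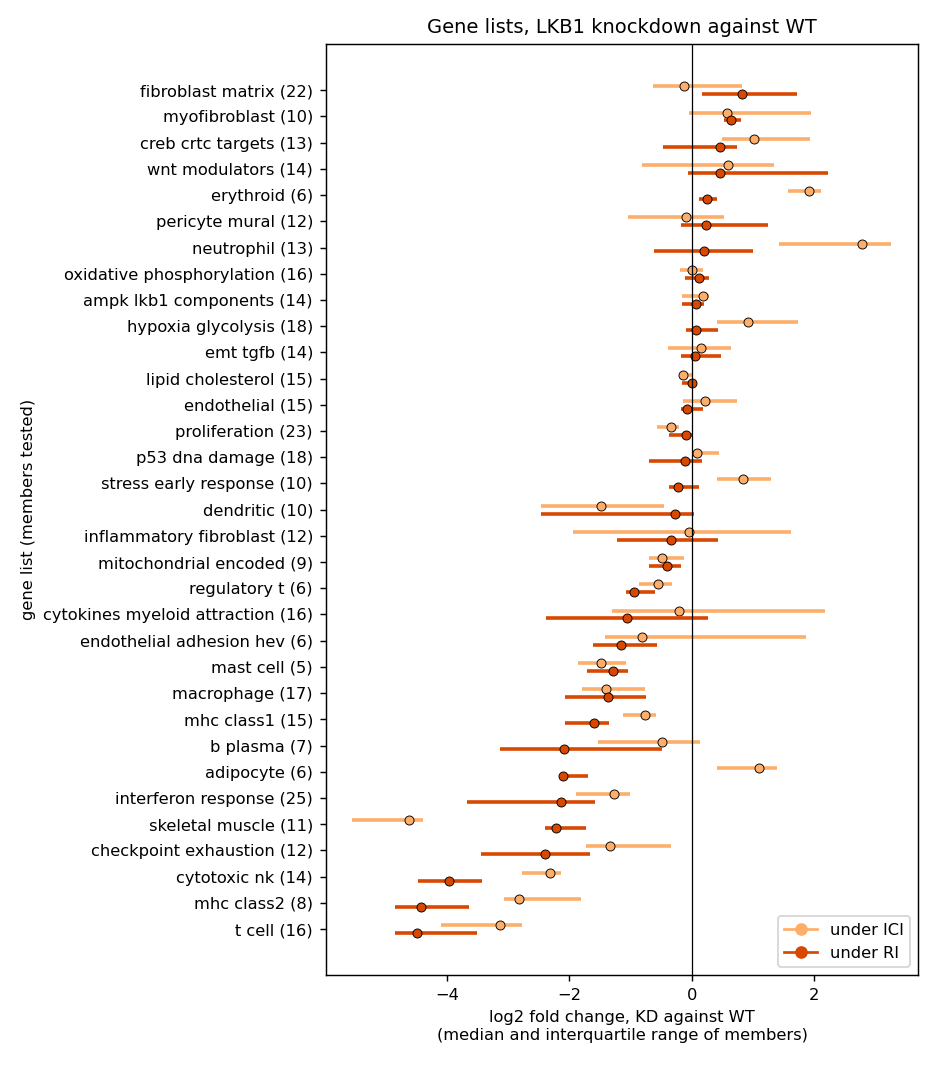
Median and interquartile range of log2 fold change, KD against WT, over the members of each list, under ICI and under RI. The number of members tested is in brackets.

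RI against ICI in WT tumours raised a few interferon-response and class I genes, and Col7a1, Col5a1 and Apoe were among those that fell. Irgm1, an interferon-induced GTPase, rose by 1.25±0.12 (adjusted p = 0.00270), from 47.3±1.08 to 112±4.84 CPM (n = 3 and 3). Cd274 rose by 1.01±0.14 (0.0200), from 27.0 to 54.3 CPM. Irf1 rose by 0.92±0.15 (0.0260), from 85.1 to 161 CPM, and Tap1, the peptide transporter of class I, by 0.80±0.12 (0.0232), from 91.2 to 158 CPM. Col7a1, an anchoring collagen, fell by 1.25±0.18 (0.0200), from 301 to 127 CPM. In all, 26 genes were higher and 21 lower, 47 past the threshold against 1844 at unadjusted p below 0.05.

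Checkpoint list genes rose in 2 of 12 cases in WT, 2 over the list alone (adjusted p = 0.000408, and 0.125 with an estimated correlation), Cd274 and Tigit (1.05±0.19, 0.0454). Class I list genes rose in 2 of 15 cases, 10 over the list alone (2.24e-13, and 0.125 with an estimated correlation); Psmb9 rose by 0.70±0.12 (0.0342). Interferon list genes rose in 2 of 25 cases, 4 over the list alone (2.79e-08, and 0.351 with an estimated correlation). The guanylate-binding genes Gbp7 and Gbp3, whose family shares sequence, rose by 1.32±0.17 (0.0156) and 1.27±0.21 (0.0260). Ido2, of tryptophan breakdown, rose by 1.87±0.31 (0.0260), Il12rb1, an interleukin 12 receptor chain, by 1.17±0.21 (0.0454), Tgm2, a cross-linking enzyme, by 1.27±0.22 (0.0413) and the stem cell receptor Lgr6 by 2.29±0.34 (0.0200). CREB list genes rose in 1 of 13 cases, Sik1 (1.01±0.18, 0.0448), 3 over the list alone (0.00146, and 0.228 with an estimated correlation).

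Fibroblast list genes fell in 1 of 22 cases in WT, 5 over the list alone (adjusted p = 0.000132, and 0.383 with an estimated correlation): Col5a1 fell by 1.03±0.17 (0.0260), from 168 to 82.1 CPM. Macrophage list genes fell in 1 of 17 cases, 3 over the list alone (0.0304, and 0.5 with an estimated correlation): Apoe, a lipid carrier, fell by 1.04±0.15 (0.0200), from 482 to 235 CPM. Mgl2, a lectin of alternatively activated macrophages, fell by 2.90±0.43 (0.0200), from 10.3 to 1.37 CPM, the growth factor Ptn by 1.61±0.21 (0.0182) and the microtubule gene Map2 by 1.41±0.14 (0.00292). Pericyte genes were lower in 12 of 12 cases, 0 past the threshold and 4 over the list alone, with a median of -0.61 (4.81e-05, and 0.125 with an estimated correlation); Pdgfrb gave -0.77±0.23 (0.215) and Rgs5 -1.09±0.35 (0.253). Dendritic genes gave 0 calls and 5 falling over the list alone (4.50e-05, and 0.125 with an estimated correlation). Cytokine, hypoxia and adipocyte genes gave 0 calls and 3, 2 and 4 rising over the list alone (1.44e-06, 1.11e-07 and 0.0356, and 0.255, 0.228 and 0.554 with an estimated correlation); Adm gave 1.42±0.32 (0.120) and Hk2 0.66±0.16 (0.137). Neutrophil, stress and proliferation lists also leaned up (8.16e-06, 0.0205 and 0.0470, and 0.281, 0.529 and 0.847 with an estimated correlation), and the muscle list down (0.0319, and 0.712). Of these, macrophage genes lost the call without WT ICI 1 (0.0834) or WT RI 1 (0.0521), adipocyte genes without KD ICI 3 (0.0778), WT ICI 1 (0.0823), WT ICI 3 (0.133) or WT RI 3 (0.876), and stress genes without WT ICI 2 (0.246) or WT RI 2 (0.0792). Muscle genes lost it without KD ICI 3 (0.0609), WT ICI 2 (0.918), WT RI 1 (0.420) or WT RI 2 (0.482), and proliferation genes without any 1 of 8 libraries, at most 0.133 (WT RI 3).

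The WT treatment counts are fragile. Leaving out 1 library moved the 47 genes to 78 (KD ICI 1), 350 (KD ICI 3), 14 (KD RI 3), 6, 6 and 7 (WT ICI 1, 2 and 3) and 3, 2 and 5 (WT RI 1, 2 and 3). With the naming series as covariate 12 genes passed, 10 of them shared with the 47, where all WT RI libraries are of JIAN and 2 of the 3 WT ICI libraries of TUI. In that fit 13 of the 21 calls of named genes were lost, those of Cd274, Tap1, Psmb9, Gbp3, Tigit, Ido2, Il12rb1, Tgm2, Lgr6, Sik1, Col5a1 and Apoe among them. Irgm1 and Map2 passed in all 12 fits without 1 library, but without both muscle-rich libraries, WT ICI 2 and WT RI 3, neither did (0.121 for each) and 0 of the 21 calls named held. Cd274 lost its call without WT ICI 1 (0.0690), WT ICI 2 (0.0566), WT ICI 3 (0.113), WT RI 1 (0.0576), WT RI 2 (0.119) or WT RI 3 (0.0809). Tap1 did so without the same libraries (0.0797, 0.0566, 0.113, 0.0720, 0.119 and 0.0809) and without KD RI 3 (0.0507). Irf1 did so without the same 7 (0.126, 0.141, 0.198, 0.123, 0.171, 0.0809 and 0.0527). Every other named gene called in this comparison lost its call without at least 4 of the 6 WT libraries, up to adjusted p = 0.251 for Il12rb1 without WT ICI 3. With library size alone Gbp3, Il12rb1 and Irf1 lost their calls. With muscle transcripts as covariate Ido2, Tgm2, Tigit, Irf1, Psmb9 and Sik1 did so, among others. With the title number as block Ido2, Gbp3, Il12rb1, Tgm2, Tigit, Irf1, Tap1, Psmb9, Sik1 and Col5a1 did so, among others. Rgs5 and Hk2 passed without KD ICI 3 (0.0187 and 0.0107), and Adm without KD RI 2 (0.0439). Of the list counts, the checkpoint, class I, interferon, CREB and fibroblast ones became 0 without any 1 WT library, and the macrophage one without WT ICI 1, WT ICI 3 or any 1 WT RI library. Without KD RI 3 the class I, interferon, CREB and fibroblast counts became 0, as did the CREB count without KD ICI 2 or KD RI 1. The checkpoint count became 1 without any 1 KD RI library and the class I count 1 without KD RI 1. Without KD ICI 3 counts rose to 7 for class I, 5 for interferon, 2 for fibroblast and 3 for macrophage genes, and without KD ICI 1 to 4 for interferon and 2 for macrophage genes.

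RI against ICI in KD tumours lowered 14 genes past the threshold. Runx3, a transcription factor of cytotoxic T cells, fell by 2.08±0.32 (adjusted p = 0.0297), from 4.36 to 1.03 CPM (n = 3 and 3). Coro1a, an actin regulator of leukocytes, fell by 1.39±0.21 (0.0297), from 38.5 to 14.6 CPM. Cd52, a lymphocyte surface antigen, fell by 1.49±0.19 (0.0131), from 13.7 to 4.87 CPM. In all, 0 genes were higher, against 2455 at unadjusted p below 0.05; DESeq2 called 450, of which 70 were higher.

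Among the 14 were Fcgr3, Cytip, Ptpn22, Cd52, Runx3, Pirb, Gmfg, Coro1a, Itgam, Vsir, Slfn2, H2-Q6 and H2-Q7. Cytip, a leukocyte adhesion adaptor, fell by 1.65±0.24 (adjusted p = 0.0247), Gmfg by 1.36±0.19 (0.0221) and Vsir, which encodes the checkpoint VISTA, by 0.85±0.14 (0.0469). H2-Q7 and H2-Q6, which share sequence, fell by 1.77±0.23 (0.0131) and 1.51±0.21 (0.0209). Checkpoint list genes fell in 1 of 12 cases, 6 over the list alone (0.000593, and 0.125 with an estimated correlation), and class I genes in 1 of 15, 9 over the list alone (7.97e-08, and 0.219 with an estimated correlation). Class II, cytotoxic, interferon, hypoxia and macrophage genes gave 0 calls and 6, 5, 5, 6 and 6 falling over the list alone, with 1 macrophage gene rising (0.000218, 3.02e-05, 8.72e-05, 1.11e-07 and 0.000362). With an estimated correlation these were 0.281, 0.278, 0.5, 0.228 and 0.297. Without KD ICI 3 checkpoint (0.0625), cytotoxic (0.0625), interferon (0.352), macrophage (0.260) and class II genes (0.0518) did not pass, while class I and hypoxia genes did. The 1 class I gene became 10 without KD ICI 3 and 0 without KD RI 1 or KD RI 3. The 1 checkpoint gene became 4 without KD ICI 3, 2 without KD RI 2 and 0 without any 1 other library except WT RI 3. Csf1r, the macrophage growth factor receptor, gave -0.79±0.17 (0.102) and Hk2 -0.54±0.17 (0.205).

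Proliferation genes were higher in 23 of 23 cases in KD, 0 past the threshold, with a median of 0.36 (adjusted p = 3.67e-08, and 0.489 with an estimated correlation); Ccnb1, a mitotic cyclin, gave 0.64±0.22 (0.244). Fibroblast and Wnt lists leaned up (0.00255 and 0.0211, and 0.491 and 0.281 with an estimated correlation), with Postn at 0.90±0.33 (0.259) and Sfrp1 at 1.55±0.52 (0.236). Neutrophil genes were lower in 13 of 13 cases, 0 past the threshold and 0 over the list alone (0.000132, and 0.358 with an estimated correlation). Stress, erythroid, CREB and T cell lists also leaned down (0.000182, 0.000526, 0.0222 and 0.0151). Their values with an estimated correlation were 0.351, 0.390, 0.358 and 0.5. Fibroblast genes lost the call without KD ICI 3 (0.306) or KD RI 1 (0.158), Wnt genes without KD ICI 3 (0.246) or KD RI 1 (0.0714), stress genes without KD ICI 3 (0.166), and T cell genes without KD ICI 3 (0.385), KD RI 1 (0.132) or KD RI 2 (0.0677). CREB genes lost it without KD ICI 1 (0.155), KD ICI 3 (0.135), KD RI 1 (0.0523) or KD RI 3 (0.0749).

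Leaving out 1 library moved the 14 genes to 26 (KD ICI 1), 3324 (KD ICI 3), 1 (KD RI 1), 120 (KD RI 2), 0 (KD RI 3), 5 (WT ICI 1 and WT ICI 3) and 6 (WT RI 1 and WT RI 2). H2-Q7 and Cd52 each lost the call without KD RI 1 (0.177) or KD RI 3 (0.158), and the other genes with values here without those and further libraries. Runx3 did so without KD RI 1 (0.262), KD RI 3 (0.248), WT ICI 1 to 3 (0.0956, 0.0667 and 0.0748) or WT RI 1 to 3 (0.0884, 0.0867 and 0.0699). With the H80 libraries KD ICI 1 and 2 summed into 1, Coro1a, Gmfg and Vsir lost their calls, and with library size alone Runx3, Coro1a and Vsir. Vsir also did so at a minimum of 1 CPM in 3 samples. Of the 8 genes with values here, the calls kept were that of Vsir with the title number as block, those of Cd52 and Coro1a without the muscle-rich libraries, and those of H2-Q7 and Cd52 with muscle transcripts as covariate. Without the SG793 libraries, which leaves 1 library in KD RI, only H2-Q6 kept its call, and with only the groups compared none did. Csf1r passed without KD ICI 3 (0.0109) or KD RI 2 (0.0487), and Ccnb1 without KD ICI 3 (0.00126).

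The effect of RI over ICI differed between KD and WT in genes of class I presentation and the interferon response, among others. Tap1 responded lower in KD by 1.45±0.18 (adjusted p = 0.00568): it went from 91.2 to 158 CPM in WT and from 54.0 to 34.2 in KD. Cd274 responded lower by 1.60±0.21 (0.00852), and H2-Q7, uncertain as above, by 2.48±0.30 (0.00568). Dmpk, a muscle-expressed kinase, responded higher in KD by 1.30±0.16 (0.00568), from 55.3 to 33.1 CPM in WT and 21 to 31 in KD. In all, 10 genes responded higher in KD and 51 lower, 61 in total against 2238 at unadjusted p below 0.05. None of the 47 WT and 14 KD genes was shared. Of the 47, 28 had the opposite sign in KD and 21 also passed the difference; of the 14, 8 had the opposite sign in WT and 9 also passed the difference.

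Class I list genes responded lower in KD in 4 of 15 cases (Psmb9, Tap1, H2-Q7, H2-T23), 13 over the list alone, with a median of -1 (adjusted p = 7.47e-16, and 0.125 with an estimated correlation). The 4 became 12 without KD ICI 3 and 2 without any 1 of the libraries KD ICI 1, KD RI 1, KD RI 3, WT ICI 1 to 3 and WT RI 1 to 3. Interferon genes did so in 3 of 25 cases, 11 over the list alone (1.77e-10, and 0.281 with an estimated correlation): Gbp3 by -2.00±0.31 (0.0246), Irf1 by -1.32±0.21 (0.0252) and Gbp2 by -2.87±0.51 (0.0452), which went from 121 to 341 CPM in WT and 17.3 to 6.68 in KD. The 3 became 5 without KD ICI 1, 7 without KD ICI 3 and 0 without any 1 of KD RI 1, KD RI 3, WT ICI 1 to 3 and WT RI 1 to 3. Checkpoint genes did so in 1 of 12 cases, 7 over the list alone (1.08e-06, and 0.0725 with an estimated correlation), with 7 cases without KD ICI 3 and 2 without KD RI 2. CREB genes did so in 1 of 13 cases, 6 over the list alone (0.000268, and 0.194 with an estimated correlation), Sik1 by -1.59±0.25 (0.0250), and stress genes in 1 of 10, Zfp36 by -1.61±0.29 (0.0452; list 2.71e-05, and 0.281 with an estimated correlation). The CREB gene became 3 without KD ICI 3 and 0 without KD RI 1, KD RI 3, WT RI 2, WT RI 3 or any 1 WT ICI library, and the stress gene 3 without KD ICI 3, 2 without KD RI 2 and 0 without KD ICI 1, KD RI 1, KD RI 3 or any 1 WT library. Hypoxia genes gave 0 calls but 14 of 18 over the list alone (4.15e-12, and 0.145 with an estimated correlation), with Hk2 at -1.2±0.23 (0.0530) and Adm at -2.31±0.44 (0.0576). Neutrophil genes gave 0 calls and 9 of 13 over the list alone (4.54e-08, and 0.226 with an estimated correlation). Runx3 responded lower by 2.64±0.43 (0.0254) and Fpr2, a chemotactic receptor, by 2.26±0.36 (0.0250).

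Fibroblast genes leaned the other way, though endothelial genes did not. All 22 fibroblast list genes responded higher in KD, 0 past the threshold and 4 over the list alone, with a median of 0.83 (adjusted p = 1.08e-06, and 0.281 with an estimated correlation); Col5a1 gave 1.01±0.24 (0.0933). The endothelial list did not pass, with 11 of 15 genes lower and a median of -0.42 (0.493). Col7a1 responded higher by 1.63±0.25 (0.0215), from 489 to 640 CPM in KD, Ptn by 1.70±0.29 (0.0369), Map2 by 1.49±0.20 (0.00910) and Igsf10, a matrix protein, by 2.53±0.41 (0.0257), from 18.8 to 5.01 CPM in WT and 8.72 to 13.5 in KD. Pericyte, dendritic, muscle and proliferation lists leaned higher (0.00263, 0.00456, 0.00433 and 0.00985, and 0.194, 0.190, 0.587 and 0.772 with an estimated correlation). Cytokine, cytotoxic, class II, p53, T cell and erythroid lists leaned lower (1.49e-05, 2.30e-05, 0.0192, 0.0291, 0.00841 and 0.0192). Their values with an estimated correlation were 0.281, 0.271, 0.489, 0.339, 0.491 and 0.535. Class II genes lost the call without KD ICI 3 (0.461), KD RI 2 (0.202), KD RI 3 (0.0663) or WT RI 2 (0.0703), p53 genes without KD ICI 3 (0.101), WT ICI 2 (0.0579) or WT RI 3 (0.104), and T cell genes without KD ICI 3 (0.200). Erythroid genes lost it without KD ICI 1 (0.0910), WT ICI 1 (0.0823) or WT ICI 3 (0.0733), muscle genes without WT ICI 2 (0.141), WT RI 1 (0.0806) or WT RI 2 (0.0736), proliferation genes without KD ICI 1 (0.692), KD ICI 2 (0.0755) or KD RI 3 (0.0802), and pericyte genes without KD ICI 3 (0.0598).

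Leaving out 1 library moved the 61 genes to 1902 (KD ICI 3), 9 (KD RI 1), 178 (KD RI 2), 13 (KD RI 3), 15, 15 and 16 (WT ICI 1, 2 and 3) and 18, 11 and 19 (WT RI 1, 2 and 3). Tap1, H2-Q7, Cd274 and Dmpk passed in all 12 of those fits, and Map2 in all but that without KD RI 1 (0.0507). Without both muscle-rich libraries all 5 missed the threshold (0.0968 for each), as did the other named calls, and H2-Q7 also did without the SG793 libraries (0.108). Gbp3 lost its call without KD RI 1 (0.0924), KD RI 3 (0.0672), WT ICI 1 to 3 (0.0692, 0.0756 and 0.0829) or WT RI 1 to 3 (0.0742, 0.0965 and 0.0652). The other named genes called here lost theirs in at least 7 of the 12 fits, up to 0.160 for Gbp2 without WT ICI 3. With library size alone Gbp3, Irf1, Gbp2 and Zfp36 lost their calls, with the naming series as covariate Gbp2 and Zfp36, and with no filter Gbp2. Without the SG793 libraries, which leaves 1 library in KD RI, Gbp2, Runx3, Zfp36, Ptn, Igsf10 and Fpr2 also did. Tap1, H2-Q7, Cd274, Map2 and Dmpk kept theirs with muscle transcripts as covariate or the title number as block, as did Gbp3 in the former and Ptn in the latter, and the other named genes did not. Hk2 passed without KD ICI 2 (0.0378), KD ICI 3 (0.00639) or KD RI 2 (0.0362), and Adm without KD ICI 3 (0.0268) or KD RI 2 (0.00766).

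**Figure D4:**
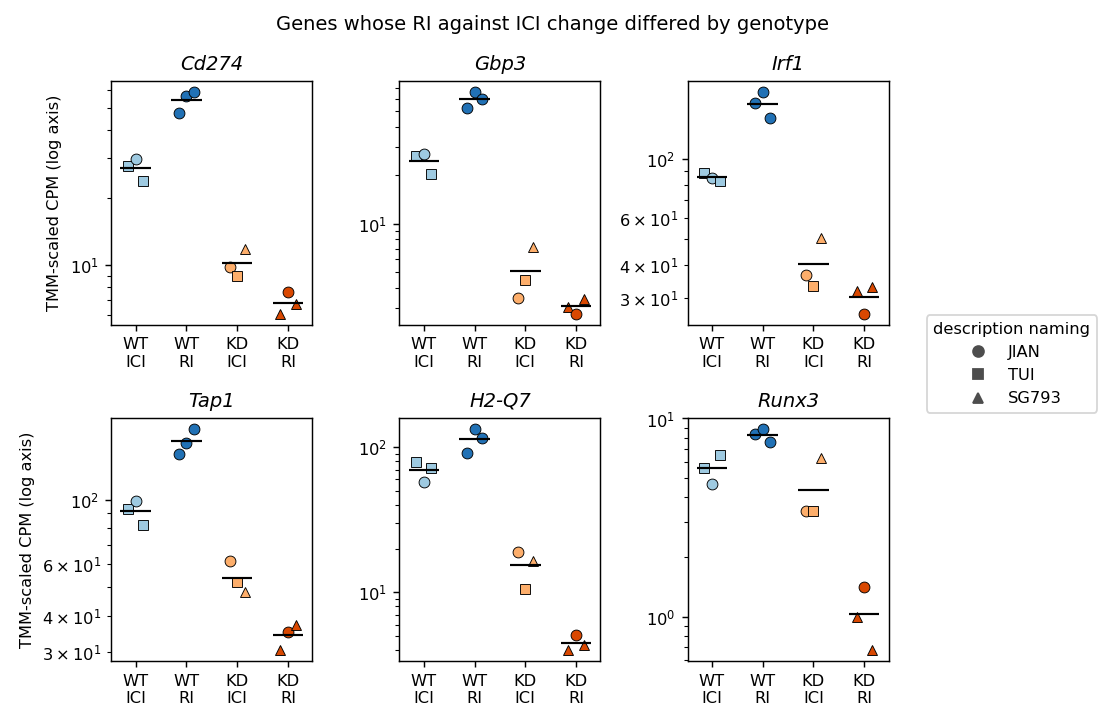
Cd274, Gbp3, Irf1, Tap1, H2-Q7 and Runx3 in CPM on a log axis, 1 point per library, in the 4 groups with counts.

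The KD tumours with radiation alone have only FPKM values, in a separate table of 34745 rows, so RI against RT and RT against ICI were left untested and levels alone are given (n = 3). Stk11 stood at 11.2±1.27 FPKM in RT, against 14.7±2.85 in KD ICI and 15.0±1.91 in KD RI. Sfrp2 was listed at 0, 0.247 and 0.0186. Pde4b was 0.755±0.478 in RT against 8.45±0.195 in KD ICI, and Vegfa 5.74±1.52 against 44.4. C1qb was 120±29.0 in RT against 49.1 in KD ICI, and Cd274 3.34±0.331 against 2.60. Col1a1, the main fibrillar collagen chain, was 0.985±0.998 in RT against 18.0 in KD ICI and 44.7 in KD RI. The housekeeping gene Actb was 192 in RT against 311 in KD ICI, and Gapdh 30.4 against 53.3. A batch cannot be told apart from treatment here, so no shift in level against RT, of any size, carries a reading of treatment. Beside WT, Pde4b in RT was near WT ICI (0.881) and WT RI (1.16), while Cd274 was nearer KD ICI than WT ICI (7.92) or WT RI (15.5).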

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

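The tests of library size, host cells and the SG793 libraries on the T cell genes, of muscle-rich and SG793 libraries on the class I and interferon genes, and of KD ICI 3 were chosen after the results were seen; the splits of the samples were planned.

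The effect of RI over ICI differed between KD and WT, by a test of the difference itself, in 61 genes. Named with their log2 difference, KD minus WT, they include Tap1 (-1.45), H2-Q7 (-2.48), Cd274 (-1.60), Gbp3 (-2.00), Irf1 (-1.32), Gbp2 (-2.87), Runx3 (-2.64), Fpr2 (-2.26), Sik1 (-1.59) and Zfp36 (-1.61). In the other direction were Dmpk (1.30), Map2 (1.49), Col7a1 (1.63), Igsf10 (2.53) and Ptn (1.70). Across 100 splits of the samples, 5 gave as many genes, the real one included, with 1355 at most in another split against 61, so chance is not excluded for the count. The 4 larger ones all exchange KD ICI 3 and KD RI 2, which parts the SG793 libraries from the rest of KD and points to a structure of the samples. With the naming series as a covariate 85 genes passed, 44 of them shared with the 61. Of the lists, 18 passed against 20 at most in another of the 100 splits, and 5 splits gave as many, so chance is not excluded there either. Groups of 3 were not tested for outlying samples.

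Class I and interferon genes, 40 over both lists, had a median log2 difference of -0.93, with 39 lower and 7 past the threshold. Muscle tissue in WT ICI 2 and WT RI 3 as the cause could not be decided by leaving those libraries out. They lie 1 in each WT group, at a mean log2 CPM of muscle genes of 6.70 and 6.05. Their muscle content thus nearly cancels in RI against ICI, and the median would move little either way. Without both libraries it was -0.90 (spread between genes 1.00), with 40 lower, so the difference is also seen in the remaining libraries. None of the 40 passed there, with a median standard error of 0.337 against 0.289 and 26 at unadjusted p below 0.05 against 28; why the calls ended was not tested. The SG793 libraries as the cause would shrink the median once they are left out. It was -0.84 without them (spread 0.660), but KD RI then holds only KD RI 2, assumed to vary like the other groups, so this cause is left open. Treatment effects of opposite direction may remain as a hypothesis, found and examined on the same libraries, since the class I median was 0.44 for RI against ICI in WT and -0.40 in KD; what they come from was not tested. The naming series is mixed into the WT part, with all WT RI libraries of JIAN and WT ICI 1 and 3 of TUI. With that series as covariate 12 genes passed in WT in place of 47, and Cd274, Tap1, Psmb9 and Gbp3 lost their calls there. For the difference, 13 of 15 calls of named genes held in that fit.

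T cell genes were lower in KD in every member on average over both treatments. Scaling between libraries as the cause would bring the median near 0 under library size alone, where it was -4.12. A lower share of all host cells would lower stromal genes alike, yet the endothelial median (-0.000149, members' standard deviation 0.445) lies 3.99 above that of T cells (-3.99, 0.694). Xist, read above as a mark of female hosts, was 51.3, 33.8 and 43.9 CPM in KD ICI 1, KD ICI 2 and KD RI 2. In WT it was 66.7 to 107 CPM, so a partial fall in host share is not excluded. The SG793 libraries as the cause would bring the median up without them; within the JIAN libraries, 2 KD against 4 WT with none of SG793, it was -4.12 as well, with all 16 genes lower past the threshold. A difference of T cell content tied to the genotype, or to another difference between the WT and sgLkb1 lines or tumours, remains a candidate explanation. These cannot be told apart here, since no sample is labelled as a line with a control guide. No library is labelled untreated either, so a difference present before treatment cannot be seen.

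Without KD ICI 3 the count of genes for RI against ICI in KD was 3324 in place of 14. KD ICI then holds only KD ICI 1 and KD ICI 2, which share H80 and may not be separate animals. The count thus rests on KD ICI 3. This library correlated with the SG793 libraries of KD RI more than with its own group, by 0.0157 on average (0.976 to 0.979 against 0.958 to 0.966), but KD RI 2 correlated with its own group (0.98 to 0.986) at least as well as with KD ICI 1 and 2 (0.977 to 0.982). A shared origin of the SG793 libraries and a wrong treatment label of KD ICI 3, whose correlation with its own group was 0.962 and whose description reads CON, which may stand for an untreated control, cannot be told apart here, since only 1 SG793 library carries the ICI label. The Y-linked Ddx3y was at 5.15, 3.55 and 2.34 CPM in the SG793 libraries and 0.636 or less elsewhere. Xist, the transcript of the inactive X, was at 1.61, 0.388 and 0.208 CPM there and from 33.8 to 107 CPM elsewhere. Hosts thus seem male in SG793 and female elsewhere, which may go with a shared origin. The low Y transcripts of WT libraries given above were left unexplained. Host sex is mixed into RI against ICI in KD and into KD against WT, and it was in no model.

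Splits of 3 against 3 libraries number 10, too few for a share under 0.05. For genes, the real count and the highest of the others were 5146 and 2 for KD against WT under ICI, 3528 and 0 under RI, 47 and 0 for RI against ICI in WT, and 14 and 2988 in KD, where 2 splits gave as many. That larger split exchanges KD ICI 3 and KD RI 2, so it sets the SG793 libraries against the rest and points to a structure of the samples; with the naming series as a covariate 76 genes passed. For lists the real and the highest other counts were 14 and 18 under ICI (3 splits as large), 11 and 19 under RI (8), 15 and 14 in WT (1) and 15 and 13 in KD (1). Averaged over treatments, the 6761 genes were met by 1 of 100 splits, the real one, with 1528 at most in the others. A chance division of these libraries is thus improbable for that count, if they are separate samples, which the labels do not say. Such splits cannot exclude chance differences between animals or between the WT and sgLkb1 lines. The 15 lists of the average were met by 18 of 100 splits, with 21 at most, so chance is not excluded for them.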

How the results depend on the processing

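The settings that leave out muscle-rich or SG793 libraries or take muscle transcripts as covariate or the JIAN libraries alone were chosen after seeing the data; the rest were planned.

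For KD against WT most named genes kept their calls, but most were picked for large change or small p in these same libraries. Calls of Stk11 on average and of Sele, Vegfa, Spp1 and Dcn were lost in some settings. Of all 5146 calls under ICI, 3085 stayed with only the groups compared and 3442 without KD ICI 1. Under ICI 42 genes gave 1008 values, of which 992 had the direction and side of the threshold reported, 9 fell short, 7 newly passed and 0 reversed; under RI it was 866 of 888, with 17, 5 and 0. On average over treatments it was 130 of 144, and the JIAN libraries alone gave 4514 genes there. For RI against ICI 446 of 648 values in WT, 278 of 384 in KD and 316 of 460 of the difference did so. DESeq2 and RLE lost 0 of the calls of named genes in any of the 6 comparisons. No list past the threshold changed the sign of its median under library size alone or RLE.

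Several counts of genes moved, and where fewer samples or genes do not give the cause it was not tested. With DESeq2 RI against ICI gave 389 genes in WT, 450 in KD and 564 for the difference, against 47, 14 and 61. Library size alone gave 9 in KD and 31 for the difference, and no filter on low counts 77, 97 and 147. Fits of only the groups compared gave 3123 for KD against WT under ICI, 828 for RI against ICI in WT and 0 in KD (2455 at unadjusted p below 0.05 and 450 by DESeq2 in all libraries); these fits give no value for the average and the difference. The naming series as covariate gave 12 in WT and 76 in KD. Without the muscle-rich libraries the counts were 0 in WT, 4 in KD and 0 for the difference, and 17 lists passed for KD against WT under RI. Without the SG793 libraries, which leaves 1 library in KD RI, assumed to vary like the others, they were 7975 for KD against WT under ICI, 428 in WT, 35 in KD (3 shared with the 14) and 95 for the difference (23 shared with the 61), and 7 lists passed in KD. Muscle transcripts as covariate gave 28, 5 and 19.

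With an estimated correlation camera called 0 lists in each of the 6 comparisons, and fry called 4 in WT, 4 in KD and 9 for the difference.

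With the title number as replicate block RI against ICI gave 23 genes in WT, 3 in KD and 21 for the difference.

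Leaving out 1 library in turn gave these ranges: KD against WT under ICI 3570 to 7827 genes, under RI 2433 to 5116 and on average 5777 to 8665; RI against ICI in WT 2 to 350, in KD 0 (without KD RI 3) to 3324, and the difference 9 to 1902. For lists they were 12 to 15, 9 to 17, 12 to 18, 12 to 16, 5 to 20 and 14 to 18. No such fit left a group with 1 sample by its label. That without KD ICI 3 gave the highest count of genes in each comparison. It leaves KD ICI with only KD ICI 1 and KD ICI 2, which share H80 and may not be separate animals.

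Changes near 0 reversed for the genes always named. Stk11 for RI against ICI in KD was 0.0289 with library size alone, and -0.1525 to 0.0488 without 1 library (0.0173 without KD RI 2), against -0.07. Its difference was -0.0207 with the naming series as covariate. Sfrp2 for RI against ICI in WT was -0.6052 without the muscle-rich libraries and -0.0973 to 0.9836 without 1 library. None of these passed the threshold.

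The FPKM pseudocount does not apply, as tests used counts. Depth limits genes of low level: on the TMM scale 1 count is up to 0.0680 CPM, so a group mean of 0.1 CPM rests on few counts.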

Other observations

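The values in this part were picked after the data were seen. Proliferation genes had a mean log2 CPM of 6.05 in KD ICI 1, 6.44 in KD ICI 2 and 7.29 in KD ICI 3, against 7.09 to 7.11 in WT ICI. Neutrophil genes ran the other way in the same libraries, at 5.12, 4.26 and 3.12, against 2.36, 1.37 and 2.05 in WT ICI. Class II genes stood at 0.98, 1.79 and 3.44 in KD ICI 1 to 3. Hbb-bs stood at 1284, 452 and 105 CPM there, but in WT ICI 2 it was 379 CPM with the lowest neutrophil level of the 12 libraries (1.37).

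In KD tumours with radiation alone, H2-Q7 was 5.02±1.17 FPKM against 1.89 in KD ICI and 0.595 in KD RI, and Tap1 5.59±0.669 against 4.20 and 2.87. Cd8a was 0.133±0.0665 FPKM in RT, against 0.0294 and 0.0268 in the other KD groups and 0.661 and 1.26 in WT ICI and WT RI. Dcn was 4.00±2.51 FPKM in RT against 22.0 and 26.2. The RT libraries list 16600, 17027 and 16646 genes above 0. Ddx3y was at most 0.00566 FPKM there, and Xist, the transcript of the inactive X, 0.290, 1.25 and 0.101 in RT 1, 4 and 5. In FPKM, Xist stood at 0.0825, 0.0207 and 0.0109 in KD ICI 3, KD RI 1 and KD RI 3 and from 1.71 to 6.02 in the other 9 libraries with counts. The RT values lay between these ranges, but RT was normalized separately.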
